A study of Mus musculus with 24 samples.

How the data were processed

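Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open chromatin and inserts sequencing adapters, in small intestinal epithelial cells of young and aged C57BL/6JRj mice. Per the labels' protocols, cells were released by EDTA and trypsin digestion and sorted as EpCam-positive and CD45-negative, a gate that keeps epithelial cells and leaves out most leukocytes. The 24 sample records describe 6 libraries sequenced on 4 lanes each, aged 1, 2 and 4 and young 1, 2 and 4. The lanes of a library share a single column of counts, so each library counted as 1 replicate (n = 3 per age). The ages, 2 to 3 months and 20 to 22 months, come from the design text of the whole series, in sentences that describe other assays. The labels do not state outright that each library came from a separate mouse, so p-values measured only the spread between these libraries.

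The deposited values are raw counts per consensus peak with no normalisation, and a companion table gives each peak's position, annotation class, nearest gene and distance to that gene's transcription start site (TSS). The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.4, BWA 0.7.17-r1188, SAMtools 1.10, bedtools 2.29.2, deepTools 3.4.3, Picard 2.23.1, R 3.6.2, MACS2 2.2.7.1, featureCounts 2.0.1 and MultiQC 1.9, with the genome build GRCm38. Whether reads or fragments were counted, the settings of the peak caller, any shift of reads for the Tn5 insertion offset and the annotation release are not given in the sources used here. A single set of 150646 peaks was counted in every library, with a median width of 223 bp (range 71 to 2232 bp). Coordinates are GRCm38 as the deposited tables give them, counted from 1.

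Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Peaks were filtered with filterByExpr, scaled by the trimmed mean of M-values (TMM) and compared between ages with edgeR's quasi-likelihood test with robust dispersions, with age as the only term. A peak or gene was called at a Benjamini-Hochberg adjusted p below 0.05, and log2 fold changes are aged over young. Standard errors (SE) are those implied by the test statistic. Normalised read counts (CPM) are the output of edgeR's cpm function with TMM-scaled library sizes, computed from the deposited counts. For a value per gene, counts were summed over peaks within 1000 bp of the gene's annotated TSS and tested in the same way. CPM of promoters are scaled to the total of promoter counts and are not on the scale of CPM of peaks.

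Before the data were examined, 29 gene lists were fixed, covering antigen presentation, interferon, inflammation, defence, senescence, signalling, metabolism, intestinal regions and cell types of the epithelium and of neighbouring tissue. They were tested at promoters with camera at a preset correlation of 0.01, where at least 5 members were tested. Camera with an estimated correlation and fry were run beside it. Of 800 list entries 726 had a symbol in the annotation, directly or through RefSeq synonyms. The named peaks were fixed by rule: among called peaks with no overlap between the ages, the 8 promoter-proximal and the 5 distal peaks with the smallest p in each direction. A peak was promoter-proximal within 1000 bp of the TSS. In each list up to 4 genes with the smallest p were named, and 17 genes were to be given whatever their value; some of these are not used here. Shares of counts were compared by exact two-sided permutation tests, whose smallest p is 0.1 with 3 libraries against 3.

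Other scalings, filters, tests, thresholds and distances, and leaving out each library, were also fixed before the data were examined. The replicate numbers occur in both ages, so a fit with the number as a block was planned too. The deviations of same-numbered libraries from their age's mean correlated at 0.236 for number 1, 0.182 for number 2 and 0.123 for number 4. All exceeded the 0.1 set as the criterion for taking the numbers to pair the libraries. The main fit nevertheless kept age as its only term, and values with the block are given as an alternative. The labels do not say what a number marks. The different-numbered pairs lay between -0.194 and 0.0287. Thinning all libraries to the depth of the shallowest and Fisher's exact tests on the peaks near list genes were added after the data had been seen.

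Total counts in peaks ranged from 6149680 in young 4 to 23935291 in aged 2, and the median count per peak from 13 to 49. No pair of libraries agreed within sampling noise, with a chi-square per peak between 1.71 and 4.12. Same-numbered libraries of different ages had 2.33, 2.204 and 2.321 for numbers 1, 2 and 4. Pairs of the same age had 1.71 to 2.655, and pairs that differed in age and number 2.273 to 4.12. Libraries that shared a number were thus about as close as libraries that shared an age. On simulated counts with the libraries' depths and dispersion, the test of 126428 peaks recovered 15.5% of 1.5-fold, 30.6% of 2-fold and 83.9% of 4-fold changes, and 4 of 86 calls were false. The test of 13793 promoters recovered 69.1%, 91.8% and 98.6%, and 15 of 190 calls were false. For peaks and for promoters alike 200 features were changed, while 2077 peaks were called in the data. The adjusted threshold depends on that number, so these shares are not the power of the real test. The camera test called the 1 list that had been changed and 0 of 20 unchanged lists. DESeq2 1.42.0 was run as an alternative test. No genome sequence was used here, so motif tests and a correction for GC content were not run.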

Results

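ATAC-seq libraries of sorted small intestinal epithelium were compared between 3 young and 3 aged libraries. The design text of the whole series gives ages of 2 to 3 and 20 to 22 months, in sentences that describe RNA-seq of epithelium and sequencing of organoids; the labels of these libraries say only young and aged. The series concerns sources of inflammation with age in the intestinal epithelium, and the comparison of ages is the only one its design gives. Counts in the 150646 consensus peaks totalled 16900796, 23935291 and 17453629 in aged 1, 2 and 4, and 22819924, 20046684 and 6149680 in young 1, 2 and 4. Young 4 was the shallowest, 3.89-fold below the deepest library. On the first principal component of log2 CPM, which held 37.9% of the variance, the aged libraries lay at -77.7, -38.0 and -53.8 and the young ones at -3.38, 25 and 148. The shallow young 4 lay farthest out, at 148, and whether this component follows age or depth was not tested. All values below rest on n = 3 libraries per age, and errors of CPM are standard deviations (SD).

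Accessibility at some peaks differed strongly between the young and the aged libraries. The promoter of Thbs3, which encodes the extracellular matrix glycoprotein thrombospondin 3, was 4.53-fold more accessible in the aged epithelium, at 18.7 ± 1.65 CPM against 4.14 ± 0.281 CPM. An intergenic peak 55685 bp from the long non-coding RNA gene Gm12153 was 9.01-fold higher in aged, at 22.8 ± 3.66 against 2.36 ± 0.540 CPM. In the other direction, the last exon of Cyp4f15, a member of the cytochrome P450 family, was 13.8-fold less accessible in aged, at 1.16 ± 0.132 against 16.1 ± 0.641 CPM. The promoter of the non-coding gene 1700030C10Rik was 15.1-fold lower, at 0.795 ± 0.0561 against 12.3 ± 2 CPM.

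Of 129588 tested peaks, 2077 (1.60%) were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1393 higher and 684 lower in aged. Their median log2 fold changes were 1.29 and -1.51. Changes above 2-fold made up 973 of the higher and 560 of the lower peaks, and changes above 4-fold 254 and 204. The 3 aged and 3 young values did not overlap at 13.9% of all tested peaks, where chance gives 10%. Among called peaks, which the test itself selects for such a difference, they did not overlap at 1370 of the higher and 681 of the lower peaks. With the replicate number as a block, 2578 peaks were called higher and 1420 lower. Without young 2 the higher calls numbered 742 and without aged 4 they numbered 886, so these libraries weighed most on that count.

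Among the named promoter-proximal peaks that rose, the Thbs3 peak lay at chromosome 3, 89224208 to 89224616, 82 bp from the TSS, with a log2 fold change of 2.18 (SE 0.15, adjusted p = 1.55e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Ddo promoter (chromosome 10, 40629724 to 40630296) rose by a log2 fold change of 1.2 (SE 0.13), to 22.0 ± 1.16 from 9.41 ± 0.721 CPM; Ddo encodes D-aspartate oxidase. The promoter of the protein-coding gene Gm14137 (chromosome 2, 119174197 to 119174750) rose by 1.92 (SE 0.21). Gm11714 on chromosome 11 had the highest log2 fold change of the group, 3.13 (SE 0.33), from a low level of 0.338 ± 0.158 CPM in young. The remaining ones were Cdk3-ps with 1.71 (exon 2 of 5 of a pseudogene of a cyclin-dependent kinase), Gm37214 with 1.59, Gm37027 with 1.59 and the peak assigned to Gm20461 with 1.93, which the annotation places at the Fkbpl promoter.

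The named distal peaks that rose lay in intergenic or intronic sequence. The Gm12153 peak (chromosome 11, 43903051 to 43903757) had a log2 fold change of 3.17 (SE 0.17, adjusted p = 7.36e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It lay in a region (43903051 to 44002417) where all 9 tested peaks were above 0 and 8 were called higher. A peak in intron 2 of 27 of Abi3bp, an extracellular matrix gene, rose by 2.82 (SE 0.19, chromosome 16, 56537950 to 56538366). It lay in a region (56501235 to 56550723) where 4 of 6 tested peaks were called higher. A peak in intron 2 of 2 of the non-coding gene 1110019D14Rik rose by 2.11 (SE 0.15; chromosome 6, 13982517 to 13982925). Intergenic peaks nearest to RP24-307I24.1 (chromosome 5, 148489247 to 148490219) and n-R5s209 (chromosome 1, 27044777 to 27045268) rose by 2.40 (SE 0.16) and 4.36 (SE 0.29). The n-R5s209 peak lay in a region (27044341 to 27058601) where all 4 tested peaks were called higher, and a copy number difference stays open there.

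Among the named promoter-proximal peaks that fell, 1700030C10Rik (chromosome 12, 20815384 to 20816003) had a log2 fold change of -3.92 (SE 0.22, adjusted p = 9.51e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The peak 75 bp from the TSS of Klhdc9, a kelch-domain gene (chromosome 1, 171360705 to 171361041), fell by 3.67 on the log2 scale (SE 0.27), while all counts within 1000 bp of that TSS together fell by 0.63. Phyhipl (chromosome 10, 70599007 to 70599901) fell by 2.33 (SE 0.19), to 1.9 ± 0.229 from 9.41 ± 1.81 CPM. The microRNA gene Mir1905 had -3.18, Gm37777 -4.69 and Gm16046 -2.30. In the region that ends with the Gm37777 peak (140226736 to 140267142 on chromosome 1) all 6 tested peaks were called lower, and a copy number difference stays open there. Smarca5-ps with -3.28 and Rps4l with -3.35 are gene copies whose reads can be shared with their source genes, and their values are uncertain.

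The Cyp4f15 peak, in exon 13 of 13 (chromosome 17, 32702659 to 32703202), had a log2 fold change of -3.79 (SE 0.18) and the smallest adjusted p of all named peaks, 6.48e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the other distal peaks that fell, the peak nearest to Gm37782 lay at the annotated promoter of Pcbp3, an RNA-binding protein gene, with -3.28 (chromosome 10, 76961756 to 76962311). The peak in exon 1 of 24 of Frem2, a basement membrane protein gene, which the annotation assigns to a processed pseudogene, had -3.38 (chromosome 3, 53656638 to 53657611). E030044B06Rik, exon 3 of 3, had -3.56 and an intergenic peak nearest to 2410018L13Rik -4.86. All 26 named peaks were called under every alternative in which they were tested. They had been chosen for their small p, so this says little of the other calls.

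**Figure D1:**
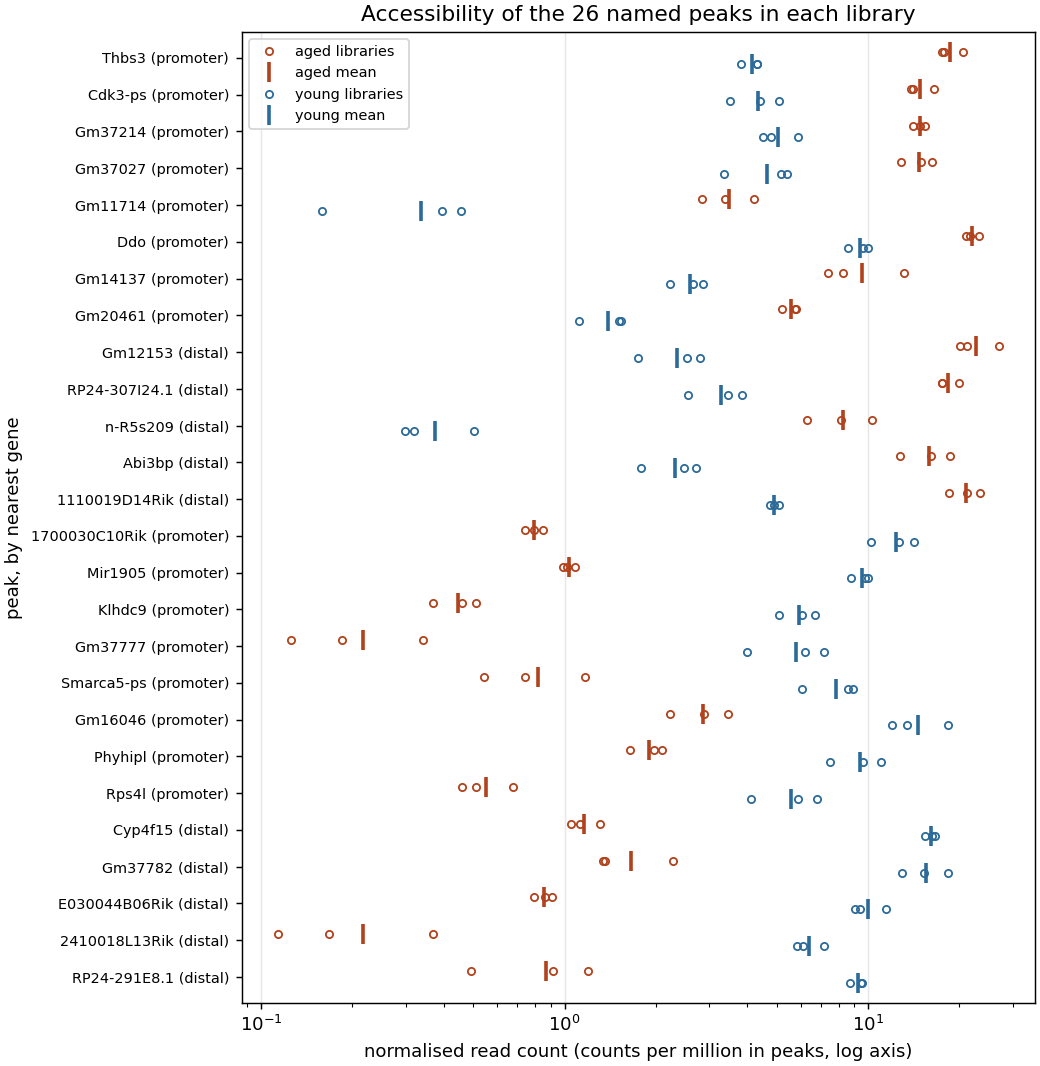
Normalised read count (CPM in peaks, log axis) of the 26 named peaks in each library, with aged libraries in red, young libraries in blue and a bar at each mean of n = 3. At every peak the libraries of the ages do not overlap, which the rule for naming peaks required. Thbs3 lies at 17.6 to 20.6 CPM in aged and 3.81 to 4.30 CPM in young.

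Peaks that rose and peaks that fell lay in different parts of the genome. Promoter-TSS peaks made up 170 (24.9%) of the peaks that fell, 119 (8.54%) of those that rose and 15.2% of all tested peaks. Intergenic peaks made up 630 (45.2%) of those that rose, 177 (25.9%) of those that fell and 34.0% of tested peaks. Exonic peaks made up 13.2% of those that fell and 6.03% of those that rose. Fisher's exact test gave an odds ratio of 3.54 (95% interval 2.72 to 4.61) for promoter-TSS against other classes, lower against higher, with a p of 8.95e-22 after adjustment over 5 classes. Peaks are not independent replicates, so these tests describe these libraries; with the replicate block the odds ratio was 2.19.

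**Figure D2:**
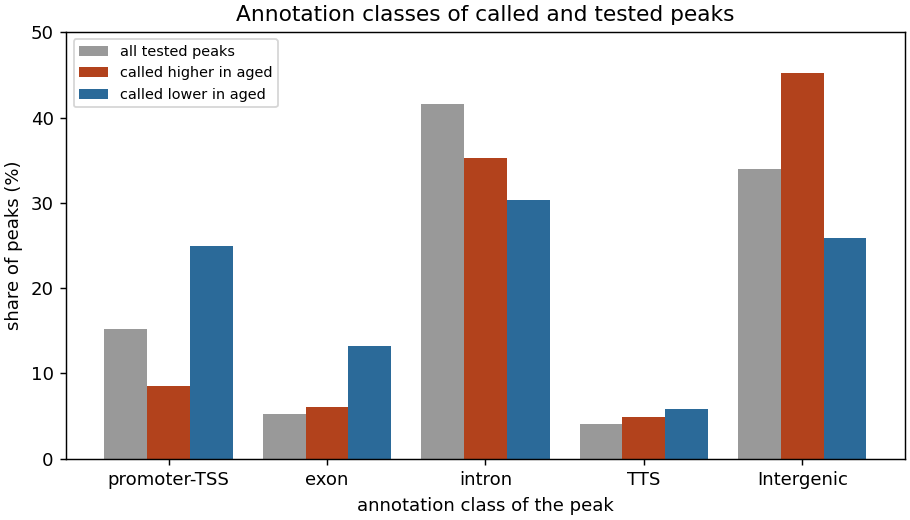
Share of peaks (%, from 0) in each annotation class for all tested peaks (grey), peaks called higher in aged (red) and peaks called lower (blue). Promoter-TSS peaks are 24.9% of the lower and 8.54% of the higher peaks, and intergenic peaks 25.9% and 45.2%.

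Chromosome X held 17 of the peaks that fell and 6 of those that rose, against 667 and 1383 on the autosomes. The odds ratio was 5.87 (95% interval 2.2 to 18.3, Fisher's exact p = 6.44e-05). Of all 129588 tested peaks 2679 lay on chromosome X, so the odds ratio comes from few rises there more than from many falls. This chromosome was singled out after its counts were seen. The share of all counts on chromosome X was 1.36% ± 0.00800 in aged and 1.38% ± 0.0172 in young (exact permutation p = 0.3). Peaks within 1000 bp of a TSS held 33.4% ± 0.936 of counts in aged and 33.6% ± 1.83 in young, a difference of -0.164 points (exact two-sided permutation p = 1, smallest possible 0.1). Without young 1 the difference was 0.825, without aged 4 0.279 and without young 4 -0.974, so its sign rests on single libraries. Chromosome Y held 0.0111% ± 0.00152 of counts in aged and 0.00806% ± 0.000669 in young, with no overlap between the ages (exact permutation p = 0.1, adjusted 0.9), and 4 of its peaks were called higher and 0 lower by edgeR's quasi-likelihood test. None of 9 such shares and totals differed after Benjamini-Hochberg adjustment, and this design could not have reached 0.05.

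At the level of whole promoters, 242 of 13880 genes were called, 107 higher and 135 lower in aged. Thbs3 rose by a log2 fold change of 2.26 (SE 0.14, 66.9 ± 10.3 against 14.1 ± 1.04 promoter CPM) and Ddo by 1.08 (SE 0.10). Phyhipl fell by 2.31 (SE 0.19) and Rps4l by 3.32 (SE 0.29). Named after their values were seen, the promoters of Eif4ebp3, whose product binds the translation initiation factor eIF4E, and Amhr2, the anti-Müllerian hormone receptor, rose by 1.99 (SE 0.20) and 1.77 (SE 0.20). The innate immune receptors Tlr6 and Tlr12 rose by 2.49 (SE 0.50) and 0.67 (SE 0.17), and the NADPH oxidase genes Noxa1 and Cyba by 0.37 (SE 0.07) and 0.36 (SE 0.09), but they were picked by function from the called genes, and in the fixed defence list of 19 promoters 0 were called (camera p = 0.745). The epithelial sodium channel gene Scnn1a rose by 0.63 (SE 0.10) and the carcinoembryonic antigen family genes Ceacam10 and Ceacam12 by 1.42 (SE 0.18) and 1.43 (SE 0.26); the peaks around Ceacam12 shared an even fold, so a copy number difference stays open there. Il6st, a receptor subunit for interleukin 6 family cytokines, fell by 2.27 (SE 0.48) and the imprinted gene Peg3 by 1.43 (SE 0.27), both likewise named after their values were seen. Of the secretoglobin genes, Scgb2b20 had 2.18 and Scgb2b11 2.81, but the members of that family are near-identical and their counts are uncertain.

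Protein-coding genes made up 64 of the promoters that rose and 103 of those that fell, with median log2 fold changes of 0.95 and -1.59 over all called promoters. The values of the ages did not overlap at 14.0% of tested promoters, where chance gives 10%, and at 106 of the 107 and all 135 called ones, which the test selects for such a difference. Promoters that fell were weak, with a median of 8.11 promoter CPM, against 22.2 for those that rose and 51.6 for all tested promoters. The calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; the replicate block gave 213 higher and 251 lower. The higher calls fell to 64 without aged 4 and 67 without young 2.

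Of the genes to be given whatever their value, those used here showed no called change at their promoters. Cd74, the invariant chain of MHC class II, had a log2 fold change of 1 (SE 0.45) at its promoter, at 49.0 ± 13.7 promoter CPM in aged and 29.0 ± 16.9 in young, with an adjusted p of 0.653 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 young values were 16.2, 22.7 and, in young 4, 48.1; without young 4 the log2 fold change was 1.36 (SE 0.23, adjusted p = 0.00576 by the same edgeR test). Over all peaks within 50000 bp Cd74 had 0.54 (SE 0.17, adjusted p = 0.151, and 0.0312 with the replicate block; without young 4, 0.76 and 0.000329, by the same edgeR test). H2-Aa had 0.15 (SE 0.21) and H2-Eb1 0.24 (SE 0.15). The stem cell genes Lgr5, Olfm4 and Ascl2 had -0.09 (SE 0.09), 0.27 (SE 0.09, adjusted p = 0.224) and 0.17 (SE 0.11). The antimicrobial lectin genes Reg3b and Reg3g had 0.11 (SE 0.26) and 0.11 (SE 0.26), and the cell cycle inhibitors Cdkn1a and Cdkn2a 0.33 (SE 0.20) and -0.04 (SE 0.18).

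**Figure D3:**
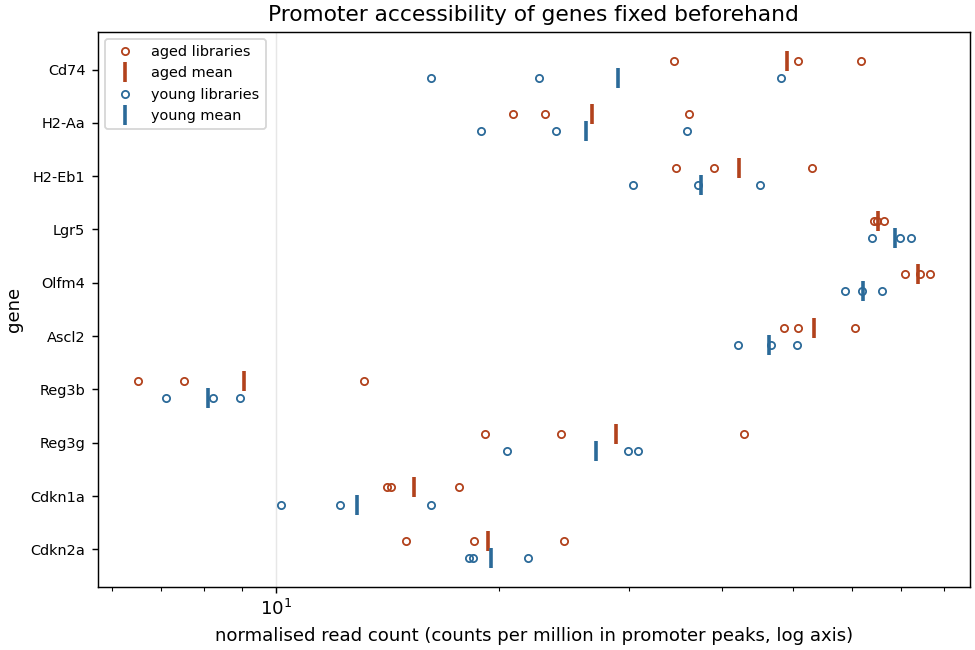
Promoter accessibility (CPM in promoter peaks, log axis) of the fixed genes used here, with aged libraries in red, young libraries in blue and a bar at each mean of n = 3. Cd74 spans 16.2 to 48.1 in young and 34.5 to 61.8 in aged, and the ages overlap at every gene except Olfm4.

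Other fixed genes had values only from peaks within 50000 bp of the TSS. Ciita, the master regulator of MHC class II, had 0.18 (SE 0.13), H2-Ab1 -0.20 (SE 0.11), Irf1 -0.07 (SE 0.09) and the T cell gene Cd3e 0.17 (SE 0.21), and none was called. Nlrc5 and Ptprc had no tested value, either at the promoter or over peaks within 50000 bp.

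No gene list was called as a whole. Over 29 lists the smallest adjusted p of camera with Benjamini-Hochberg adjustment was 0.406, for the ribosomal protein genes, which was also the only list with an unadjusted p below 0.05 (p = 0.014). Camera with an estimated correlation and fry each called 0 lists, with 0 at an unadjusted p below 0.05. Without aged 1, camera called goblet cells higher (median 0.14) and ribosomal proteins lower (median -0.09), each with an adjusted p of 0.0385. Without young 4, MHC class II had the smallest camera p (p = 0.00193, adjusted p = 0.0524); without young 1 its median was -0.06. Of the 501 list genes with a tested promoter, Plaur was called higher and Igfbp7, Isl1 and Prox1 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Median, mean and camera direction did not share a sign for lipid absorption, xenobiotic metabolism, circadian clock, Paneth cells, duodenal identity, fibroblasts, myeloid cells and neurons.

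Immune and inflammatory lists were not called. Over their promoters the median log2 fold change was 0.16 for MHC class II (6 genes), the highest of the 29, -0.05 for MHC class I (17), -0.014 for the interferon gamma response (28), -0.05 for the type I interferon response (30), 0.05 for NF-kB and TNF signalling (27) and 0.04 for antimicrobial defence (19). In the type I interferon list the exonuclease gene Isg20 had 0.33 (SE 0.10, adjusted p = 0.120, and 0.00862 with the replicate block, by edgeR's quasi-likelihood test), Dhx58 0.34 (SE 0.11), Oas1g -0.50 (SE 0.20) and Gm14446 -0.43 (SE 0.18). By the same edgeR test Oas1g was called lower without young 1 (-0.77, adjusted p = 0.0240) and Isg20 higher without aged 1 (0.42, adjusted p = 0.0234). The chemokine gene Cxcl16 of the NF-kB list had 0.42 (SE 0.12, adjusted p = 0.0792, and 0.0150 with the replicate block, by edgeR's quasi-likelihood test), and it was the 1 gene of that list called when adjusted over the list alone. Next to it stood Nfkb2 with 0.15 (SE 0.06), Tnfrsf1b with 0.21 (SE 0.09) and Nfkbiz with 0.31 (SE 0.16). For the interferon gamma list, Igtp had -0.49 (SE 0.20), Cxcl9 0.39 (SE 0.17), Gbp7 -0.23 (SE 0.15) and Gbp2 -0.34 (SE 0.22). Psmb10 of MHC class I had -0.24 (SE 0.13), and Duoxa2, Tlr3 and Reg1 of the defence list had 0.34 (SE 0.13), -0.19 (SE 0.08) and -0.33 (SE 0.19).

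Single peaks near NF-kB and TNF genes rose. A peak in intron 2 of 2 of Tnf, the tumour necrosis factor gene (chromosome 17, 35200446 to 35200750), rose by a log2 fold change of 2.17 (SE 0.21), to 8.01 ± 1.45 from 1.86 ± 0.343 CPM. The other 5 lay near Relb (0.65, in an intron of Clptm1), Nfkbia (0.89), Traf2 (0.97), Tnip1 (0.97) and Cxcl16 (0.50). In all, 6 of the 229 tested peaks within 50000 bp of the list's genes were called higher and 0 lower by edgeR's quasi-likelihood test, 2.62% against 1.05% of other peaks. That share did not pass Fisher's exact test after adjustment over 58 tests (adjusted p = 0.682). Camera over genes' peaks within 50000 bp gave this list the smallest p of the 29 (p = 0.00381, Benjamini-Hochberg adjusted p = 0.111), with 2 genes called higher. These peaks were named after their values were seen.

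Senescence, stress and growth lists held few called genes. In the senescence list (22 genes, median 0.015) Plaur, the urokinase receptor gene, rose by a log2 fold change of 0.53 (SE 0.13, adjusted p = 0.0341) and Igfbp7, an insulin-like growth factor binding protein gene, fell by 1.16 (SE 0.25, adjusted p = 0.00661), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and both also called when adjusted over the list alone. Plaur was not called without aged 4 (0.34), young 1 (0.54), young 2 (0.55) or young 4 (0.52), and Igfbp7 not without young 2 (-1.08). After thinning neither was called (Plaur 0.56, adjusted p = 0.125; Igfbp7 -0.76, adjusted p = 0.461, by edgeR's quasi-likelihood test), nor was Plaur with a mean of at least 50 counts (adjusted p = 0.0822 by the same edgeR test). Cdkn2c and Cdkn2b had 0.16 (SE 0.08) and 0.18 (SE 0.09). In the immediate early list (31 genes, median 0.03) the heat shock gene Hspa1a had -0.41 (SE 0.11, adjusted p = 0.0618, and 0.00870 with the replicate block, by edgeR's quasi-likelihood test) and was called when adjusted over the list alone; Egr3 had 0.43 (SE 0.16). Ribosomal protein genes (35, median -0.08) were led by Rps9 with -0.28 (SE 0.08, adjusted p = 0.0970, and 0.0213 with the replicate block, by edgeR's quasi-likelihood test). Proliferation genes (19) had a median of -0.04, with Birc5 at -0.22 (SE 0.10), and Wnt and Notch genes (29) a median of -0.03, with Wnt3 at -0.45 (SE 0.18).

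No called promoter was found in the metabolic and regional lists. Medians were 0.05 for fatty acid oxidation (23 genes), -0.0031 for lipid absorption (22), -0.00083 for xenobiotic metabolism (29), -0.018 for the circadian clock (15), 0.0098 for duodenal and jejunal identity (13) and 0.03 for ileal and colonic identity (16). Vnn1, a pantetheinase gene, had 0.30 (SE 0.14), Agpat2 0.22 (SE 0.08), Nfe2l2, the NRF2 gene, -0.23 (SE 0.10) and the clock repressor gene Nr1d1 0.25 (SE 0.11). Without young 1 Agpat2 was called higher (0.34, adjusted p = 0.0446 by edgeR's quasi-likelihood test). The vitamin D hydroxylase gene Cyp27b1 had -0.53 (SE 0.26) and Amn, a vitamin B12 uptake gene of the ileum, 0.23 (SE 0.10).

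Of the epithelial cell type lists, only enteroendocrine cells held a called promoter. Isl1, a transcription factor gene of hormone-producing cells, fell by a log2 fold change of 1.34 (SE 0.23, adjusted p = 0.000687 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), to 5.25 ± 0.768 from 13.4 ± 0.695 promoter CPM, and was also called when adjusted over the list alone. In the same list (21 genes, median -0.04) Scg3 had -0.90 (SE 0.33, adjusted p = 0.283, and 0.0116 with the replicate block, by edgeR's quasi-likelihood test) and Pax6 0.32 (SE 0.12). Medians were -0.05 for stem cells (17 genes), 0.05 for Paneth cells (8), 0.07 for goblet cells (19), 0.11 for tuft cells (15) and 0.03 for absorptive enterocytes (21). The tuft cell genes Trpm5 and Pou2f3 had 0.34 (SE 0.16) and 0.28 (SE 0.14), the goblet cell genes Foxa1 and Foxa3 0.14 (SE 0.07) and 0.15 (SE 0.09), and the enterocyte gene Nt5e 0.34 (SE 0.14).

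Markers of cells outside the epithelium seldom had a tested promoter, as with 5 of 38 T cell and 8 of 33 myeloid genes. In aged, some were more open than the median of 51.6 promoter CPM of all tested promoters (Derl3 184, Bcl11b 70.3), and others were weak (Cd2 8.91). Their medians are therefore no sure measure of other cells in the sort. Medians were -0.03 for T cells (5 genes), 0.09 for B and plasma cells (8), -0.020 for myeloid cells (8), 0.03 for fibroblasts and smooth muscle (9), -0.19 for endothelial cells (7) and -0.0016 for neurons and glia (7). Prox1, a transcription factor gene of lymphatic endothelium that enteroendocrine cells use too, fell by a log2 fold change of 0.84 (SE 0.20, adjusted p = 0.0180 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was called when adjusted over the list alone; it was not called without aged 1 (-0.69), aged 4 (-0.77), young 1 (-0.87) or young 2 (-0.89), nor after thinning (-0.70, adjusted p = 0.416 by edgeR's quasi-likelihood test). The B cell gene Cd37 had 0.40 (SE 0.12, adjusted p = 0.0888, and 0.00467 with the replicate block, by edgeR's quasi-likelihood test) and was called when adjusted over the list alone. Fcmr had 1.02 (SE 0.44) from 1.1 ± 0.126 promoter CPM, Cd68 0.40 (SE 0.20), and the mesenchymal gene Twist1 -1.12 (SE 0.41, adjusted p = 0.299, and 0.0492 with the replicate block, by edgeR's quasi-likelihood test).

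**Figure D4:**
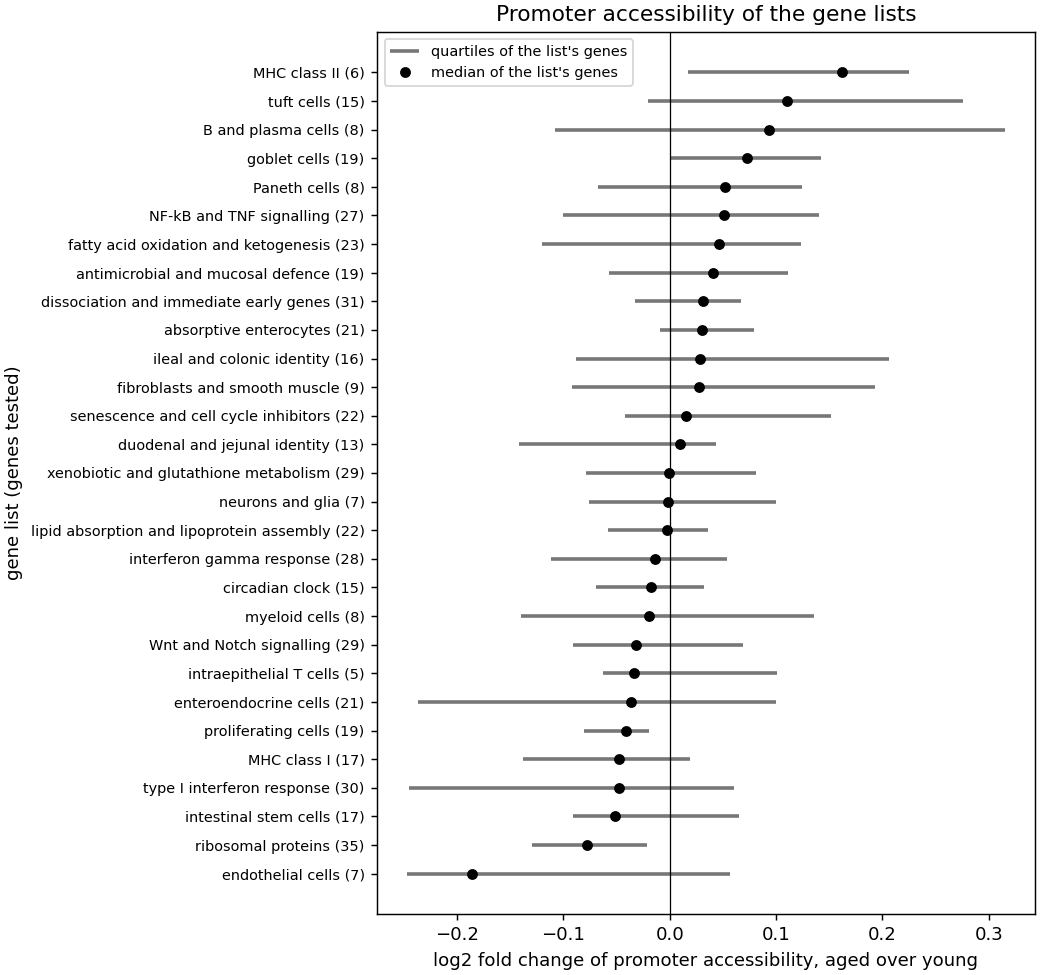
Log2 fold change of promoter accessibility, aged over young, for the 29 fixed lists, with the number of genes tested in brackets, the median as a point and the quartiles of the genes as a line. Medians range from -0.19 for endothelial cells to 0.16 for MHC class II, and no list was called.

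Called peaks of the same direction lay side by side in several regions, which were chosen after their values were seen. In the Hoxd cluster, developmental genes that pattern the body axis, all 8 tested peaks between 74655562 and 74698405 on chromosome 2 were below 0, and 4 were called. The Hoxd11 peak fell by 3.46 on the log2 scale (SE 0.39), the Hoxd9 peak by 1.77 (SE 0.30) and an exonic peak 1530 bp from the TSS of Evx2 by 1.62 (SE 0.31), while the Hoxd13 peak had -0.22 (SE 0.23). In a region across Ly6e on chromosome 15 (74930879 to 74992308), 10 of 20 tested peaks rose: 8 upstream of Ly6e, 1 in a Ly6e exon (2.82, SE 0.36) and 1 nearest to Gm37042 (1.73, SE 0.41). The Ly6e promoter peaks, with 0.31 (SE 0.13) and 0.64 (SE 0.30), were not called, and the 20 peaks ranged from -1.18 to 4.35. All calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested peaks.

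**Figure D5:**
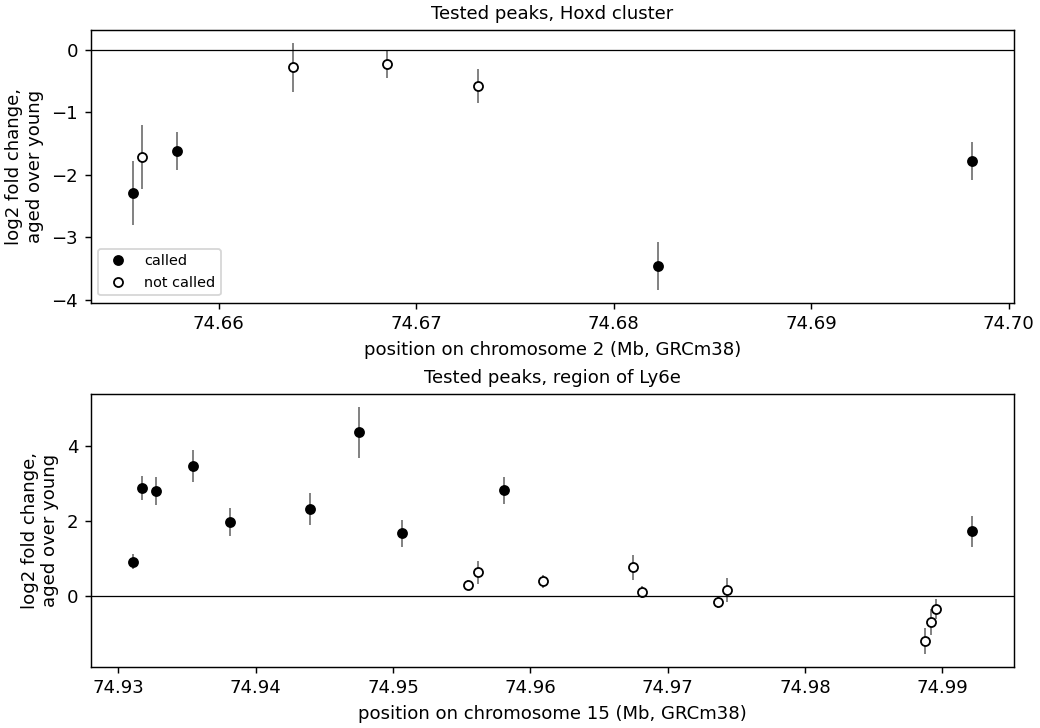
Log2 fold change (aged over young, with SE as the line) of each tested peak against its position (Mb, GRCm38) at the Hoxd cluster and the region across Ly6e, with called peaks filled. The fold changes differ between neighbours at Hoxd (-3.46 to -0.22) and Ly6e (-1.18 to 4.35).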

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

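The odds ratios of promoter-TSS peaks under settings other than the stricter threshold and the tests of peaks near list genes were chosen only after the result was seen, and thinning was added once the depths were known. No call changed sign under any setting of the peak or promoter fit. Peaks higher and lower numbered 1393 and 684; they became 2578 and 1420 with the replicate block, 558 and 202 with a mean of at least 50 counts, 507 and 247 after thinning, and 803 and 439 at an adjusted p below 0.01. Higher peaks numbered 830 by DESeq2's Wald test and 911 when tested against a 1.2-fold change. Promoters, at 107 and 135, became 213 and 251 with the block, 66 and 56 with the count minimum, 47 and 67 after thinning, 289 and 211 with peaks within 50000 bp, and 167 higher within 3000 bp. Fewer features were tested with the count minimum and after thinning (63129 and 86771 peaks), and thinning also removed depth; the other causes were not tested. Leaving out each library gave 742 to 1462 peaks higher and 474 to 646 lower, 64 to 131 promoters higher and 94 to 131 lower, and 0 to 1 lists higher and 0 to 1 lower. The difference in the share of counts near a TSS, -0.164 points, ranged from -0.974 to 0.825 and was above 0 without aged 4 (0.279) and without young 1 (0.825). Under the other scalings and with no filter every count stayed within 1.5 times its value. The pairing by block called 0 lists and changed no call of a named gene or list other than those given with the results. The promoter-TSS odds ratio lay between 2.19, with the block, and 4.22, without young 4, and leaving out a library gave 2.39 to 4.22. A pair of tests of it, chosen after the difference was seen but before their own values were, and given here as values only, were an odds ratio within strata of abundance of 4.07 (3.11 to 5.33) and a median of all promoter-TSS peaks minus all other peaks of -0.0077. Of the values of named genes, 1974 kept their side of the threshold, 18 were called only under an alternative and 13 were no longer called under an alternative; a further comparison of 1928 values called in neither setting found 50 with another sign, which were not counted as reversals. Motif tests, the correction for GC content and the block with that correction were not run, since no genome was used here. On simulated counts 30.6% of 2-fold changes were recovered at peaks and 91.8% at promoters. Depth per feature, dispersion, the number of tests and the share of features changed all differ between them and were not separated.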

Other observations

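The tests of immune and stromal cells, of transcription factor families and of stretches were chosen only after the result was seen; those of depth, scaling and other splits were set out before their own values were seen. Peaks near list genes differed in places that the promoter values did not show, and they were named after their values were seen. Upstream of Ccr2, a chemokine receptor gene of monocytes, a peak 21670 bp from the TSS (chromosome 9, 124080179 to 124080381) was close to absent in young, at 0.0153 ± 0.0264 CPM, and at 2.34 ± 0.275 CPM in aged. Its neighbour 21339 bp from the TSS rose by a log2 fold change of 1.88 (SE 0.27). In exon 6 of 12 of Csf2ra, a cytokine receptor gene, accessibility fell by 2.02 on the log2 scale (SE 0.14; chromosome 19, 61225763 to 61226705), and in exon 2 of 6 of H2-Ab1 by 1.56 (SE 0.17). A peak 7180 bp from Onecut2, a transcription factor gene of the proximal intestine, fell by 1.62 (SE 0.16), and peaks in introns 3 and 5 of the stem cell gene Tnfrsf19 by 3.93 (SE 0.44) and 1.30 (SE 0.29). The sugar transporter gene Slc2a5 had 2 peaks that fell, by 0.91 (SE 0.18) and 0.51 (SE 0.13), while a peak 5577 bp from Mki67 rose by 1.24 (SE 0.24) and peaks near Guca2b rose by 2.06 (SE 0.50) and 0.61 (SE 0.15).

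Other ways of splitting the 6 libraries into groups of 3 gave fewer calls of peaks and promoters. The real split called 2077 peaks, and 1 of the 10 splits, the real one, gave as many, with 44 as the highest of the others. It called 242 promoters, matched again by 1 split, with 1 as the highest of the others. With 10 splits the share is never under 0.1, which is all that can be said of chance. The 3 other splits that part all 3 numbered pairs gave 0 peaks and 0 promoters each; the 6 splits that part 1 pair gave 0 to 44 peaks. All 10 splits gave at least as many lists as the real 0, which a count of 0 makes certain and which says nothing of chance. Aged 1, young 1 and young 2 against the rest gave 7 lists, the highest of the others, which points to a structure of the libraries other than age. The second principal component, with 21.4% of the variance, parts them in the same way, at 4.98, 87.4 and 52.0 against -28.4, -76.6 and -39.3.

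More peaks rose than fell with age (67.1% of calls). Unequal depth of the counts is argued against by the thinned libraries, in which 67.2% of calls were higher. Thinning left the set of peaks unchanged, so an effect of depth on which peaks entered that set was not tested and stays open. The lowest share under 3 other scalings, 66.4%, argues against the scaling. Leukocytes left in the sort of aged mice, which the CD45 gate should remove, would raise peaks near T, B and myeloid genes; the 89 such peaks in the same abundance range, of 40 genes, had a median log2 fold change of -0.015 (95% bootstrap interval -0.10 to 0.07), below the 0.65 set as the bound, and 2 of them were called higher and 0 lower. The bound came from the median of the called higher peaks (1.29), which were selected for a difference, while the 89 peaks were not. A rise at only some of the 89 peaks would leave their median near 0, so it cannot decide on leukocytes. Single peaks of such genes did rise (Itgae 1.17 with SE 0.26, Prf1 1.56 with SE 0.40, Ccr2 1.88 with SE 0.27), while the Csf2ra peak fell by 2.02 (SE 0.14). At any abundance, 2 of 66 peaks within 50000 bp of T cell genes were called higher and 0 lower. For myeloid genes 2 of 96 were called higher and 1 lower, and for B and plasma cell genes 0 of 64 either way. The background share called higher was 1.05%. Leukocytes stay open. A bias from GC content, since no genome was used here, and the age of the mice, as an untested biological explanation, both stay open.

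Genes of 21 families of developmental transcription factors were called lower at 12 of 113 promoters, 10.6% against 0.893% of other genes (Hoxd11, Hoxd1, Sox30, Ebf2, Zic1, Hoxd9, Irx2, Isl1, Tbx18, Prox1, Sim1 and Meis1) and higher at 1 (Otx1), with a median log2 fold change of -0.05 over all 113. With the replicate block 14 were called lower and 4 higher. The families were chosen after the called genes were seen, so neither that count nor the odds ratio of 7.91 within strata of the mean count says whether chance or different power at different abundance explains it, and both stay open. Fewer stromal, endothelial or neural cells in the sort of aged mice would lower peaks near their marker genes. The EpCam gate should leave such cells out. The 86 such peaks had a median of 0.055 (95% bootstrap interval over peaks -0.0039 to 0.13), above the bound of -0.82, and 2 were called higher and 0 lower. That bound came from 12 peaks selected as called lower, while the 86 were not selected, so the test cannot decide. Prox1 is both among the 12 genes and in the endothelial list, and such cells stay open. A shift of the epithelial cell types themselves was not tested and stays open, as does age.

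Called peaks of the same direction lay in 28 stretches (at least 4 called peaks with gaps of up to 50000 bp), 23 higher and 5 lower. They held 145 called peaks, and 0 of 1000 shuffles within chromosome and abundance gave as many, with 17 as the highest. This argues only against calls placed independently of each other, under a rule chosen after the pattern was seen. Neighbouring peaks can belong to the same locus, so the shuffles do not tell how many separate changes the stretches hold. A single change in copy number over all called peaks of a stretch would shift every peak between them by the same fold. Peaks with at least 1 CPM in both ages departed from that in 12 stretches. In 5 (Gm12153 and Ctsh among them) called peaks differed in fold beyond their errors, which argues against such a change there. In 8 an uncalled peak stayed below 0.5 of the called mean, as at Hoxd13 (-0.22, SE 0.23), Zfp667 (0.13, SE 0.12) and Ly6i in the Ly6e stretch (-0.15, SE 0.16, called mean 2.04). Part of that gap is built in, since called peaks were selected for a difference and uncalled ones for lacking it. Smaller gaps, as at Pisd-ps1 (-0.144, SE 0.14, called mean 0.62) and Gm13835 (-0.113, SE 0.144, called mean 0.757), therefore cannot decide. In 8 others, Hs3st2 among them, such peaks were too few or did not differ, and copy number stays open; in the remaining 8, among them Ceacam12, Kcnt2 and a stretch nearest to Sod1 whose 5 peaks fell by 3.63 to 4.71 on the log2 scale, an even fold is consistent with a copy number difference. A strain or donor variant was not tested, and both it and age stay open.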
